A study of Mus musculus and Homo sapiens with 18 samples.

How the data were processed

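RNA was sequenced from primary cultures of mouse and human dorsal root ganglia in 3 conditions per species with 3 replicates each, 18 libraries in all. Total RNA was extracted and made into strand-specific libraries with a total RNA kit, per the labels' protocols. Reads were aligned with STAR 2.6.1c to GRCm38.p5 for mouse and GRCh38.p10 for human, per the submitters' processing notes. The annotation release and the options of the alignment are not given in the sources used here. The authors deposited 1 table of whole-number read counts per gene for each library, with columns for unstranded, forward and reverse reads, as STAR writes them. The reverse column (column 4) was used because it held nearly all reads. The forward column held 2.97% to 3.17% of the gene reads in mouse libraries and 4.23% to 4.62% in human libraries.

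The 4 total lines of each table were kept out of library sizes and tests. They gave unmapped reads (3.70% to 4.03% of reads in mouse, 4.25% to 6.79% in human), reads mapped to several places (10.7% to 14.6% and 7.29% to 9.00%), reads outside genes (4.04% to 5.48% and 3.72% to 4.68%) and reads that fit more than 1 gene (1.03% to 1.10% and 2.10% to 2.27%). Also left out were 92 spike-in control sequences and, in human, 62 identifiers of genes tied to sex. Mouse gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38, matched by gene identifier for 53274 of 53379 identifiers. Human identifiers were not named, because no human gene annotation was at hand, so human results are given as counts and for 4 identifiers. For the same reason the planned tests of a difference between species, and of mouse-called genes as a set in human, were not run, and the fixed genes and gene lists were followed in mouse alone.

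Reads assigned to genes numbered from 12079843 to 14789220 per mouse library and from 11854699 to 18763915 per human library. The 10 most abundant genes took 3.67% to 6.54% of mouse reads and 8.83% to 13.1% of human reads. Counting intervals are at 95% and cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Libraries of 1 group differed by more than counting noise, with chi-square per degree of freedom from 13.9 to 51.6 in mouse and from 18.4 to 63.9 in human. This does not tell technical from biological spread, and each library was entered as 1 sample without knowing whether replicates came from separate cultures.

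Groups, comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. Each species was fitted on its own with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries scaled by TMM (factors 0.939 to 1.04 in mouse, 0.947 to 1.03 in human), and the robust quasi-likelihood test was applied to all 3 conditions together. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. This planned main fit had no block and 6 residual degrees of freedom. CPM values were computed with the TMM factors. SE denotes the standard error of a log2 fold change in the fit named beside it. It was derived as the size of that change over the square root of its F statistic, so it restates the test.

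Conditions shared replicate numbers in the labels, so it was checked whether numbers pair the libraries, before calls of the fits were compared. Deviations from the condition means correlated at 0.471 to 0.768 between mouse libraries of the same number and at -0.595 to 0.16 between the others. In human the values were 0.493 to 0.743 and -0.531 to -0.118. Every same-number correlation was over 0.1, so the numbers were taken to pair the libraries, from the data and the shared numbers, since the labels do not say what a number stands for. The biological coefficient of variation went from 0.22 to 0.0824 in mouse and from 0.215 to 0.0936 in human when the replicate number entered as a block, which left 4 residual degrees of freedom. The first principal component held 40.6% of the variance in mouse, where it set replicate 3 apart, and 37.3% in human. Because the fit without the block called almost no gene, values and named genes were taken from the fit with the block, and counts without it are given beside them.

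Named genes followed 5 parts of a rule. The first was 14 fixed genes given in each comparison. The second was the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 1, a symbol that is not of a predicted gene or pseudogene, and libraries of the compared conditions fully apart. The third was up to 3 members of each list per direction with the smallest p among those past the threshold, or 1 with the smallest p where none passed. The fourth, genes that differ between species, was not applied. The fifth was the 3 most abundant members of each of 7 cell type lists. In all 31 gene lists were fixed, and 30 had at least 5 tested members. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Camera compares a list with the other genes, while fry asks whether the genes of a list move one way on balance and compares them with no other genes.

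The fits were tested on simulated data. Counts were drawn with the library sizes and the mean of each gene per replicate number, with no difference between conditions, and with the spread of the fit with the block, so the simulated libraries are paired by construction. A set of genes was then changed in KCl by known folds and tested for KCl against media. With the block, the mouse fit on 15110 genes recovered 61.2%, 83.6% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 20 false calls among 14910 unchanged genes. Without it, 7.46%, 29.9% and 72.7% were recovered with 0 false calls. The human fit on 16044 genes recovered 53.7%, 85.1% and 95.5% with the block, with 18 false calls among 15844 unchanged genes. The human fit without it recovered 0%, 38.8% and 80.3%, with 0 false calls. As numbers of genes, the fit with the block recovered 41, 56 and 63 in mouse beside its 20 false calls. In human it recovered 36, 57 and 63 beside its 18. In both species the false calls were a larger share of all calls than the threshold allows. Calls of the fit with the block, named genes included, may therefore hold more false ones than the threshold states.

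Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter or at least 1 CPM in 3 libraries, unstranded counts, only the 2 groups compared, the most abundant genes (over 1% of a library, and mitochondrial genes) left out, an added log2 fold change of at least 1, and each library left out in turn. The same alternatives in the fit with the block, the removal of trends with GC content and length, and the removal of all libraries of 1 replicate number were added after the data were seen. Overlaps between the comparisons with media were set beside independent lists and beside 20 simulations of unchanged groups. These drew all libraries anew, media included, with the drawn media libraries shared by both comparisons and each gene drawn on its own. All scalings moved the median of all genes by less than 0.1 on the log2 scale. Some named genes, and a test that rests on them, are not reported here.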

Results

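RNA was measured in primary cultures of dorsal root ganglia, which hold the cell bodies of the sensory neurons for touch, temperature and pain, from mouse and from human. Each species had 3 conditions with 3 replicates, 18 libraries in all. Cultures stayed in control media for 24 h (media), were held in 30 mM KCl for 24 h (KCl), or were held in KCl for 24 h and returned to control media for another 24 h (recovery). The media group thus matched KCl in stated length, but not recovery. Raised extracellular potassium depolarises neurons, and the question set by the design was which transcripts change when neurons are kept depolarised and which return afterwards. The labels mark all cultures with day 4 and do not say whether recovery cultures were a day older at collection than the others. Reads assigned to genes numbered from 12079843 to 14789220 per mouse library and from 11854699 to 18763915 per human library. The labels do not say whether replicates came from separate cultures, animals or donors, so the p-values measure only the spread between these samples, which may be technical.

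In mouse cultures, the comparison of recovery with KCl gave the most genes past the threshold, and KCl against media the fewest. The planned main fit had no block and called almost no gene. Values were therefore taken from a fit with the replicate number as a block, since libraries with the same number deviated together (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of 15110 mouse genes tested, 470 differed between KCl and media (243 higher in KCl, 227 lower). Between recovery and media 1994 differed (833 higher in recovery, 1161 lower), and between recovery and KCl 3387 (1584 higher, 1803 lower). Most changes were modest. Of these genes, 103, 217 and 297 respectively also changed by at least 1 on the log2 scale, and the median size of the called changes was 0.545, 0.443 and 0.424. Without the block, edgeR called 0, 0 and 1 mouse genes in the same order, where 664, 1305 and 2091 had an unadjusted p under 0.05 and DESeq2 called 28, 169 and 405. The 1 gene was Bves. The count of 470 fell to 219 without media replicate 1, 92 without media replicate 2, 138 without KCl replicate 2 and 186 without KCl replicate 3. The count of 1994 fell to 942 without media replicate 1, 1016 without media replicate 2 and 925 without recovery replicate 1, and the count of 3387 to 1968 without KCl replicate 3. Values for mouse genes below come from the fit with the block. Among the named genes past its threshold, the smallest adjusted p without the block was 0.509 for KCl against media, 0.307 for recovery against media and, Bves (0.0435) apart, 0.0636 for recovery against KCl.

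**Figure D1:**
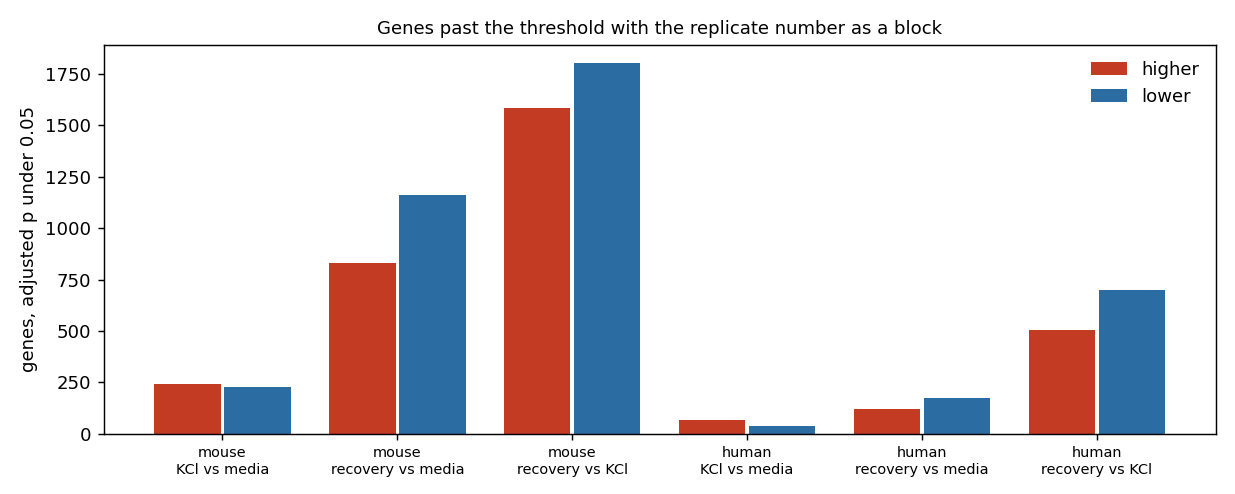
Number of genes past an adjusted p of 0.05 in each comparison, counted in the fits with the replicate number as a block, with genes higher (red) and lower (blue) in the condition named first. The tallest bars are those of mouse recovery against KCl, 1584 higher and 1803 lower; without the block the 6 comparisons gave 0 genes, or 1 in that comparison.

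After 24 h of KCl, several neuropeptide genes were higher in mouse cultures. Tac1, the gene for the pain transmitter substance P, rose from 16.1 ± 8.46 to 31.0 ± 14.7 CPM (SD, n = 3 each), a log2 fold change of 0.98 ± 0.137 (SE, edgeR adjusted p = 0.00227). Calca and Calcb, which encode the alpha and beta forms of calcitonin gene-related peptide, rose by 0.44 ± 0.0785 (adjusted p = 0.00774) and 0.95 ± 0.111 (adjusted p = 0.000381). Of 14 neuropeptide genes tested, 6 rose and 0 fell, the others being Scg2, Vgf and Adcyap1, and 9 rose when adjusted over the list alone. The median log2 change was 0.435, between 0.379 and 0.436 in the 3 replicate pairs. The set test camera gave an adjusted p of 7.33e-14 with its preset correlation between genes, and an adjusted p of 0.151 with an estimated correlation (0.228 without the block, where 0 of the genes passed). Tac1 lies on chromosome 6 from 7554879 to 7565834, plus strand (ENSMUSG00000061762.12, GRCm38, protein coding). The call of Calca ended without media replicate 1 or media replicate 2 (adjusted p up to 0.0919).

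Genes known to respond to neuronal activity moved in both directions. Bdnf, the gene for a secreted neurotrophin, rose from 30.9 ± 4.09 to 53.7 ± 5.27 CPM (log2 fold change 0.80 ± 0.101, edgeR adjusted p = 0.000607). Pcsk1, a protease that cuts peptide precursors, rose by 1.29 ± 0.15 (adjusted p = 0.00208), and Scg2, a granin of secretory vesicles, by 0.90 ± 0.117 (adjusted p = 0.00335). The transcription factor gene Npas4 rose from 1.76 ± 0.9 to 4.30 ± 0.635 CPM (1.31 ± 0.265, adjusted p = 0.0143). Fos, an immediate early gene, did not pass (0.24 ± 0.116, adjusted p = 0.316). The early response gene Egr1 fell by 0.61 ± 0.0722 (adjusted p = 0.000387), and its relative Egr3 from 21.9 ± 5.05 to 11 ± 2.75 CPM (adjusted p = 0.000813). Of 41 activity-regulated genes tested, which share Scg2 and Vgf with the neuropeptide list, 10 rose and 2 fell, or 13 and 3 adjusted over the list alone. Camera gave an adjusted p of 1.4e-06, and an adjusted p of 0.415 with an estimated correlation. The count of 10 became 5 without media replicate 1 and 4 without media replicate 2, KCl replicate 2 or KCl replicate 3, and Npas4 lost its call without any of the same 4 libraries (adjusted p up to 0.11). The call of Pcsk1 ended with only the 2 groups compared (adjusted p = 0.0539) and without all libraries of replicate 2 (0.0552). Bdnf lies on chromosome 2 from 109674700 to 109727007, plus strand (ENSMUSG00000048482.14), and Npas4 on chromosome 19 from 4984355 to 4990316, minus strand (ENSMUSG00000045903.8), in GRCm38.

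Some ion channel genes passed the threshold in KCl against media, where 470 of all 15110 genes tested did. Trpv1, the receptor for heat and capsaicin, fell from 47.3 ± 10.5 to 28.4 ± 3.71 CPM (log2 fold change -0.72 ± 0.119, edgeR adjusted p = 0.00649), and was the 1 gene of 21 sensory transduction channels past the threshold. Of 36 potassium channel genes, 4 fell, among them Kcnip1 (-0.94) and Kcnt1 (-0.40), and 1 rose, Kcna4 (0.56). None of 13 voltage-gated sodium channel genes passed edgeR's test (1 rose adjusted over the list alone). The pain-related sodium channel genes Scn9a, Scn10a and Scn11a had log2 fold changes of -0.03, -0.11 and 0.09, and Scn8a had -0.01. Of 14 calcium channel genes 1 fell, Cacna1b (-0.37), while Cacna1c had -0.09. The opioid receptor gene Oprm1 (-0.08) and the injury-induced gene Atf3 (-0.26 ± 0.0883, adjusted p = 0.133) did not pass. The adjusted p from camera was 0.902 for potassium, 0.665 for sodium, 0.748 for calcium and 0.259 for sensory channels. In the first 3 the median and camera's direction differed in sign. Fry with the block gave an adjusted p of 0.00994 for sensory (0.952 without it), 0.905 for potassium, 0.128 for sodium and 0.798 for calcium. Its test for changes in either direction, also with the block, gave 2.13e-05 for potassium, 0.000168 for sensory, 0.0808 for sodium and 0.0505 for calcium. Adjusted over the list alone, 2 potassium channel genes rose and 5 fell, 1 sensory channel gene rose and 2 fell, and 1 calcium channel gene fell. The 4 falls became 1 without media replicate 1 or media replicate 3 and 0 without media replicate 2, KCl replicate 2 or KCl replicate 3, and Trpv1 lost its call without media replicate 2 (adjusted p = 0.0591). Sodium channel rises became 2 and 1 without recovery replicates 2 and 3, calcium channel falls 2 without KCl replicate 1, sensory channel falls 2 without KCl replicate 1 or recovery replicate 2, and potassium channel rises 2 and 3 without recovery replicates 2 and 3. The calls of Kcnip1, Kcnt1 and Cacna1b ended without media replicate 2 or 3 or KCl replicate 2 or 3, as did that of Kcnt1 without media replicate 1, and that of Kcna4 without any of the 6 libraries compared (adjusted p up to 0.182, 0.179, 0.259 and 0.145). Trpv1 lies on chromosome 11 from 73234292 to 73261242, plus strand (ENSMUSG00000005952.15, GRCm38).

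Some synaptic, subtype and injury genes passed in KCl against media. Of 26 synaptic vesicle genes 3 rose, Unc13a, which primes vesicles for release (0.81 ± 0.0808, edgeR adjusted p = 0.000221), Rab3c (0.48) and Syt7 (0.35), and 1 fell, Unc13c (-0.89), or 6 and 3 adjusted over the list alone. Camera gave an adjusted p of 0.0444 (0.168 without the block), and an adjusted p of 0.461 with an estimated correlation. Of 22 sensory neuron subtype genes 1 rose, Spp1, the gene for osteopontin (0.63 ± 0.0927, adjusted p = 0.00215), and 1 fell, the artemin receptor gene Gfra3 (-0.47), or 1 and 2 adjusted over the list alone (camera adjusted p = 0.952). Of 30 genes of axon injury and regeneration 1 rose, Il6, and 2 fell, Sprr1a (-0.65 ± 0.0789, adjusted p = 0.000448) and Gap43, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.27). Without single libraries the calls of Rab3c (media replicate 1, adjusted p = 0.0526), Syt7 (media replicate 2 or 3, KCl replicate 2 or 3, up to 0.129), Unc13c (all but KCl replicate 1, up to 0.18) and Gfra3 (media replicate 2, KCl replicate 3, up to 0.0754) ended, as did that of Gap43 without media replicate 1 or 2 or KCl replicate 3 (up to 0.0991). Without KCl replicate 1 the falls of subtype genes became 3 and those of injury genes 5, and the rises of injury genes 2, as they did without any recovery replicate, where subtype falls became 2, 2 and 3 for replicates 1, 2 and 3.

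**Figure D2:**
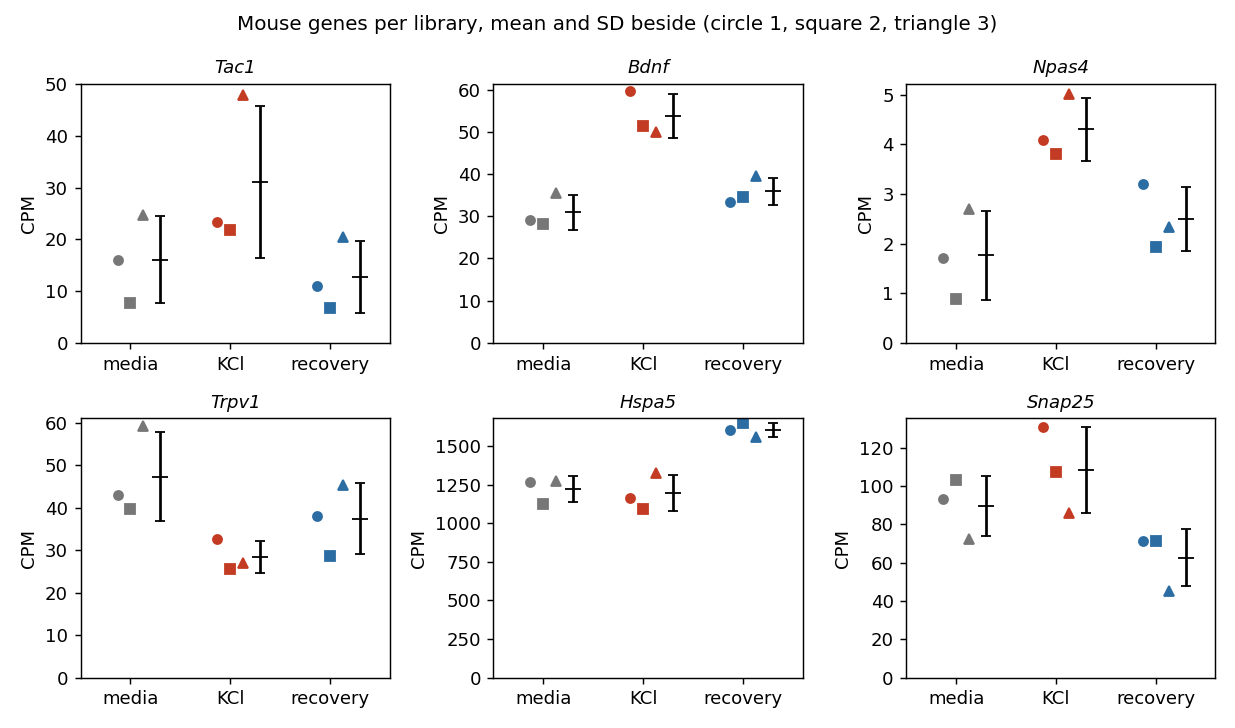
CPM (y axis) of Tac1, Bdnf, Npas4, Trpv1, Hspa5 and Snap25 in each mouse library, with symbols for replicates 1 (circle), 2 (square) and 3 (triangle), and the mean and SD of each condition beside them. Mean Bdnf was 30.9 in media, 53.7 in KCl and 35.9 in recovery, and mean Trpv1 was 47.3, 28.4 and 37.4.

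Within the limits of the rule for named genes, the largest rises in KCl were immune genes that were near 0 in media. Ccl5, a chemokine, went from 0.212 ± 0.135 to 9.74 ± 8.76 CPM (log2 fold change 5.37 ± 0.666, edgeR adjusted p = 0.0117). Tgtp1 and Ifi205, both induced by interferon, rose by 3.71 and 3.56 (adjusted p = 0.00144 and 0.0326). Both have close paralogs, and reads mapped to several places were not counted. Cxcl9, another interferon-induced chemokine, had 1 read over the media libraries and 57 over the KCl libraries, a ratio of 62.4 with a 95% counting interval of 10.8 to 2510. The 23 interferon response genes had a median log2 change of 2.38, but 0 passed edgeR's test in either direction, alone or adjusted over the list alone. Camera gave an adjusted p of 4.21e-12, and an adjusted p of 0.415 with an estimated correlation. Their summed level was 353 to 418 CPM in the media libraries and 858, 4261 and 683 CPM in KCl replicates 1, 2 and 3. Of 17 cytokine genes 3 rose, Ccl5, Il6 (0.96 ± 0.143, adjusted p = 0.00331) and Ptgs2 (0.48), and 4 adjusted over the list alone, with camera adjusted p = 0.000152 and an adjusted p of 0.415 with an estimated correlation. The calls of Ccl5, Cxcl9 and Tgtp1 ended without KCl replicate 2 (adjusted p up to 0.108, 0.322 and 0.141), as they did without media replicate 3 for Ccl5 and media replicate 2 for Cxcl9 and Tgtp1. Those of Ifi205 and Ptgs2 ended without media replicate 1 or 2 or KCl replicate 2 or 3 (adjusted p up to 0.259 and 0.184), and without recovery replicate 3 1 interferon gene rose.

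Other large changes in KCl were spread over unrelated genes. Aldh3a1, an aldehyde dehydrogenase, went from 1.08 ± 1.01 CPM in media to 11.4 ± 7.41 in KCl and 0.936 ± 0.522 in recovery (KCl against media 3.40 ± 0.252, edgeR adjusted p = 1.6e-05). Alkal2, a ligand of the receptor ALK, went from 11.4 ± 4.69 to 31.6 ± 3.67 CPM, and 12.4 ± 4.17 in recovery (KCl against media adjusted p = 0.00391). Ngef, a guanine nucleotide exchange factor, and Erfe, the hormone erythroferrone, rose by 1.34 and 1.33. Within the abundance and separation limits of the rule for named genes, the largest falls were those of Sectm1b (-2.21) and the nucleotide receptor P2ry6 (-1.48). Next within these limits were the monocarboxylate transporter family gene Slc16a6 (-1.38 ± 0.146, adjusted p = 0.000221), Abhd11os (-1.36), Draxin (-1.03), Cdh1 (-0.95, E-cadherin), Gpr139 and Egr3. Of 19 heat shock genes 2 rose, Hspa1b (1.02) and Hspa4l (0.40), or 3 adjusted over the list alone, with camera adjusted p = 0.000139 and an adjusted p of 0.415 with an estimated correlation. Reads of Hspa1b that also map to its near-identical copy Hspa1a were not counted. Without single libraries, the calls of Abhd11os and Gpr139 (any of the 6 libraries, adjusted p up to 0.143 and 0.193), Draxin (media replicate 1 or 2, KCl replicate 2 or 3, up to 0.174) and P2ry6 (KCl replicate 2, 0.0636) ended. So did those of Hspa1b (media replicate 2 or 3, KCl replicate 3, up to 0.125) and Hspa4l (media replicate 1 or 3, KCl replicate 1 or 3, up to 0.139). Aldh3a1 lies on chromosome 11 from 61207537 to 61218421, plus strand (ENSMUSG00000019102.10, GRCm38).

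Marker genes of the other cells in these cultures also differed between KCl and media. The 18 macrophage genes had a median log2 change of -0.90 in KCl, and 4 of them fell, among them Cx3cr1, the fractalkine receptor (-2.18 ± 0.224, edgeR adjusted p = 0.000221), and Csf1r, the receptor for the growth factor CSF1 (-0.92). Adjusted over the list alone 15 fell and 1 rose. Of 18 Schwann cell genes 3 fell, the myelin genes Prx (-0.72) and Mbp (-0.69) and the adhesion gene Ncam1 (-0.41), or 6 adjusted over the list alone. Of 16 satellite glia genes 1 rose, Slc1a3 (0.55), and 3 fell, Apoe (-0.63), Glul (-0.48) and Ptprz1 (-0.72), while of 19 fibroblast genes 1 fell, Mfap5 (-0.62). Adjusted p values from camera were 9.94e-15 for macrophages, 1.88e-05 for Schwann cells and 0.000774 for fibroblasts (0.21 without the block), each with an adjusted p of 0.415 with an estimated correlation, and 0.453 for satellite glia. Adjusted over the list alone, 3 satellite glia genes rose and 3 fell, and 2 fibroblast genes fell. Genes expressed across neurons had a median of 0.0579, and of 22 tested 2 rose, Elavl4 (0.50) and Isl1 (0.91), and 1 fell, Gap43 (-0.39), or 5 and 2 adjusted over the list alone (camera adjusted p = 0.382). The 4 falls of macrophage genes became 1 without media replicate 2 or KCl replicate 2, 2 without KCl replicate 3 or recovery replicate 1, 7 without media replicate 3 and 9 without recovery replicate 3, where the falls of fibroblast genes became 2. The calls of Csf1r (media replicate 2, KCl replicate 2 or 3, adjusted p up to 0.118), Ncam1 (media replicate 2, 0.0549), Ptprz1 (any media replicate, KCl replicate 2 or 3, up to 0.21), Slc1a3 (any of the 6 libraries, up to 0.166), Elavl4 (media replicate 1 or 2, up to 0.0636), Isl1 (media replicate 1, KCl replicate 1 or 2, up to 0.105) and Gap43 (media replicate 1 or 2, KCl replicate 3, up to 0.0991) ended without single libraries.

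Recovery was compared with media to see what differed a day after KCl was taken away. In mouse, most genes of neurons and their synapses were lower in recovery than in media. Nefm, a neurofilament subunit, fell from 386 ± 198 to 237 ± 149 CPM (log2 fold change -0.76 ± 0.0749, edgeR adjusted p = 6.9e-05), and Stmn2, a growth cone protein, by 0.64 ± 0.0718 (adjusted p = 0.000118). Of 22 genes expressed across neurons, 15 fell and 0 rose, or 19 adjusted over the list alone, with a median of -0.42 and values of -0.38 to -0.49 in the 3 replicate pairs. Of 26 synaptic vesicle genes, which share Snap25, Syt1 and Syn1 with that list, 17 fell and 0 rose, or 20 adjusted over the list alone, among them Syn1 (-0.57 ± 0.0662, adjusted p = 0.000143), the vesicle protein gene Sv2b (-0.94) and Napb (-0.56). In camera, the adjusted p was 8.04e-19 and 2.69e-15. With an estimated correlation it was 0.0173 and 0.0367 with the block and 0.291 and 0.188 without it, so both calls ended there. Of 30 genes of axon injury and regeneration 12 fell, among them Sprr1a (-1.06 ± 0.0797, adjusted p = 8.24e-06), Gap43 (-0.64) and Atf3 (-0.72 ± 0.0889, adjusted p = 0.000209), and 2 rose, Anxa1 (0.55) and Csf1 (0.40), or 14 and 2 adjusted over the list alone (camera adjusted p = 1.14e-08, and an adjusted p of 0.0288 with an estimated correlation, or 0.357 without the block). Over the same libraries the median change of fibroblast genes lay above 0, and those of glial and macrophage genes below. The 17 falls became 11 without media replicate 1 or recovery replicate 1, and the call of Csf1 ended without media replicate 2 or recovery replicate 2 (adjusted p up to 0.109). Nefm lies on chromosome 14 from 68082590 to 68124846, minus strand (ENSMUSG00000022054.11, GRCm38).

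Among channel and subtype genes of sensory neurons, more fell than rose in each list tested. Median log2 changes were -0.297 for sodium, -0.282 for potassium, -0.244 for calcium and -0.313 for sensory channels and -0.433 for subtype genes. That of genes expressed across neurons was -0.42, and whether channel genes fell beyond it was not tested. Of 13 sodium channel genes 7 fell and 0 rose, or 8 adjusted over the list alone, among them the auxiliary subunit genes Scn4b (-0.95 ± 0.122, edgeR adjusted p = 0.000374) and Scn3b (-0.63), the channel partner Fgf13 (-0.64) and Scn8a (-0.42, adjusted p = 0.0313). Scn9a (-0.29, adjusted p = 0.0655), Scn10a (-0.03) and Scn11a (0.00) did not pass. Of 36 potassium channel genes 10 fell and 0 rose, or 14 adjusted over the list alone, including Kcnab1 (-0.58) and Kcnip4 (-0.63). Of 14 calcium channel genes 4 fell, among them Cacna2d3 (-0.58), or 7 adjusted over the list alone, while Cacna1c had -0.01. Of 21 sensory transduction channels 7 fell, among them the ATP-gated P2rx3 (-0.49), and 1 rose, the mechanically gated Piezo1 (0.39), or 10 and 1 adjusted over the list alone, while Trpv1 had -0.34 (adjusted p = 0.0723). Of 22 sensory neuron subtype genes 10 fell and 0 rose, or 14 and 2 adjusted over the list alone, among them Slc17a8 (-1.01) and Cntnap2 (-0.63). With camera, the adjusted p was 3.21e-05, 4.68e-06, 0.000484, 0.000573 and 1.68e-07 in that order, and adjusted p values of 0.0479, 0.0636, 0.185, 0.0574 and 0.0288 with an estimated correlation. The counts of falls dropped for sodium to 3 without media replicate 1 or 2 and 4 without recovery replicate 1, for potassium to 6 without media replicate 2, for sensory channels to 3 and for subtype genes to 6 without recovery replicate 1. For calcium channels they dropped to 1 without media replicate 2 or recovery replicate 1 and 2 without media replicate 3 or recovery replicate 2. The call of Scn8a ended without media replicate 1 or 2 or recovery replicate 1 or 2 (adjusted p up to 0.202), and that of Piezo1 without media replicate 1 (0.0628).

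Neuropeptide genes that had been higher in KCl were not higher in recovery than in media. Tac1 (-0.34, adjusted p = 0.147), Calca (-0.08, adjusted p = 0.579) and Bdnf (0.22, adjusted p = 0.179) did not differ from media in edgeR's test, nor did Npas4 (0.52, adjusted p = 0.254) or Oprm1 (0.41, adjusted p = 0.42). Of 14 neuropeptide genes 5 fell and 0 rose, or 6 adjusted over the list alone, among them neurotensin (Nts, -0.69 ± 0.0872, adjusted p = 0.000247), Adcyap1 (-0.56) and galanin (Gal, -0.48). Camera gave an adjusted p of 0.000113, and an adjusted p of 0.0927 with an estimated correlation. Of 41 activity-regulated genes 3 rose, Ptgs2 (0.63), Junb (0.34) and Gadd45b (0.35), and 3 fell, Fos (-0.67 ± 0.119, adjusted p = 0.00448), Nr4a1 (-0.55) and Vgf (-0.24), with the same counts adjusted over the list alone (camera adjusted p = 0.381). The 5 falls became 3 without KCl replicate 3, recovery replicate 1 or recovery replicate 3. The 3 rises of activity genes became 1 without media replicate 1 or 2 or recovery replicate 1, 5 without media replicate 3 and 8 without recovery replicate 3, and the 3 falls became 1 without media replicate 1 or 2 or recovery replicate 1. The calls of Junb, Nr4a1, Gadd45b and Vgf ended without media replicate 1 or 2 or recovery replicate 1, as did that of Gadd45b without media replicate 3 or recovery replicate 2 and that of Vgf without recovery replicate 2 or 3 (adjusted p up to 0.0935, 0.0808, 0.249 and 0.311).

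Most genes of the unfolded protein response, which act in protein folding in the endoplasmic reticulum, and most marker genes of fibroblasts rose in recovery. Of 20 genes of the unfolded protein response 13 rose and 0 fell, or 17 adjusted over the list alone, with a median of 0.328 and values of 0.277 to 0.322 in the 3 pairs. Among them were Creld2 (0.50 ± 0.0821, edgeR adjusted p = 0.00124) and the chaperone genes Hsp90b1 (0.44) and Hyou1 (0.36). Camera gave an adjusted p of 1.29e-09, and an adjusted p of 0.0288 with an estimated correlation. Of 19 fibroblast genes 13 rose and 1 fell (Dpt, -0.80), or 13 and 4 adjusted over the list alone. The most abundant, the collagen genes Col1a1 and Col1a2 and fibronectin Fn1, rose by 0.82, 0.69 and 0.68, and Mfap5 by 0.62 ± 0.0691 (adjusted p = 0.000118). Of 11 genes of mural cells, the contractile cells around vessels, 4 rose, among them the actin gene Acta2 (0.65), and 2 fell, Myh11 (-0.73) and Rgs5 (-0.56), or 5 and 2 adjusted over the list alone. From camera came adjusted p values of 1.29e-09 for fibroblasts, with an adjusted p of 0.0837 with an estimated correlation, and 0.0551 for mural cells. The 13 rises of unfolded protein response genes became 8 without media replicate 1 and 6 without media replicate 2. The 1 fall of a fibroblast gene became 0 without media replicate 1 or 2 or recovery replicate 1, and 2 and 3 without media replicate 3 and recovery replicate 3. The 2 falls of mural genes became 1 without media replicate 2 or 3 or recovery replicate 1, where the call of Rgs5 ended (adjusted p up to 0.126), and that of Dpt ended without media replicate 1 or 2 or recovery replicate 1 (up to 0.105).

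Within the same limits, interferon-induced genes were also the largest rises in recovery, and some genes of macrophages and glia fell. Ifi44 went from 0.695 ± 0.217 to 53.4 ± 62.3 CPM (log2 fold change 6.19 ± 0.895, edgeR adjusted p = 0.0218), Ccl5 rose by 6.05, Tgtp1 by 5.12, Oasl1 by 4.87, Ifi205 by 4.73, the transcription factor gene Irf7 by 4.58 and Tgtp2 by 4.05, with the limit on paralogs given above. Cxcl9 had 219 reads over the recovery libraries, a ratio to media of 229 with a 95% counting interval of 40.6 to 9070. Of 23 interferon response genes 4 rose and 0 fell, or 19 adjusted over the list alone, with a median of 2.94 and summed levels of 2567, 4771 and 919 CPM in recovery replicates 1, 2 and 3. Of 18 macrophage genes 9 fell and 0 rose, or 13 adjusted over the list alone, among them Cd68 (-0.95), Csf1r (-0.92) and Cx3cr1 (-0.98), with a median of -0.98. Of 16 satellite glia genes 6 fell and 0 rose, the same counts adjusted over the list alone, among them Apoe (-0.80), Glul (-0.49) and Sox2 (-0.35), and of 18 Schwann cell genes 4 fell, among them S100b (-0.38), again the same adjusted over the list alone. Camera's adjusted p was 2.48e-13 for interferon, 2.39e-13 for macrophages, 3.78e-05 for satellite glia and 0.00963 for Schwann cells (0.0572 without the block), and adjusted p values of 0.22, 0.113, 0.0927 and 0.275 with an estimated correlation. Other large falls were Scara5 (-2.29 ± 0.234, adjusted p = 0.000125), the platelet factor gene Pf4 (-2.12), Crispld1 (-1.99), Cd36 (-1.63), the serotonin-gated channel Htr3a (-1.55), Atp13a4 (-1.48), Il16 (-1.43) and Kcnip2 (-1.41). The 4 interferon rises became 0 without media replicate 1, KCl replicate 3, recovery replicate 1 or recovery replicate 2 and 1 without recovery replicate 3, and the calls of Ifi44, Oasl1, Irf7 and Tgtp2 ended without media replicate 1, recovery replicate 1 or recovery replicate 2, and except for Tgtp2 without recovery replicate 3 (adjusted p up to 0.111, 0.136, 0.143 and 0.141). Those of Ifi44 and Oasl1 also ended without media replicate 2, and those of Oasl1 and Irf7 without media replicate 3. The 9 macrophage falls became 4 without media replicate 2 and 3 without recovery replicate 1, the 6 falls of satellite glia genes 3 without media replicate 1 or recovery replicate 1, and the 4 of Schwann cell genes 1 without media replicate 2, 2 without media replicate 1 or recovery replicate 1 or 2, and 7 without recovery replicate 3. The calls of Cd36 (media replicate 2 or any recovery replicate, up to 0.154) and Cx3cr1 (media replicate 2 or recovery replicate 1, up to 0.0973) ended as well.

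**Figure D3:**
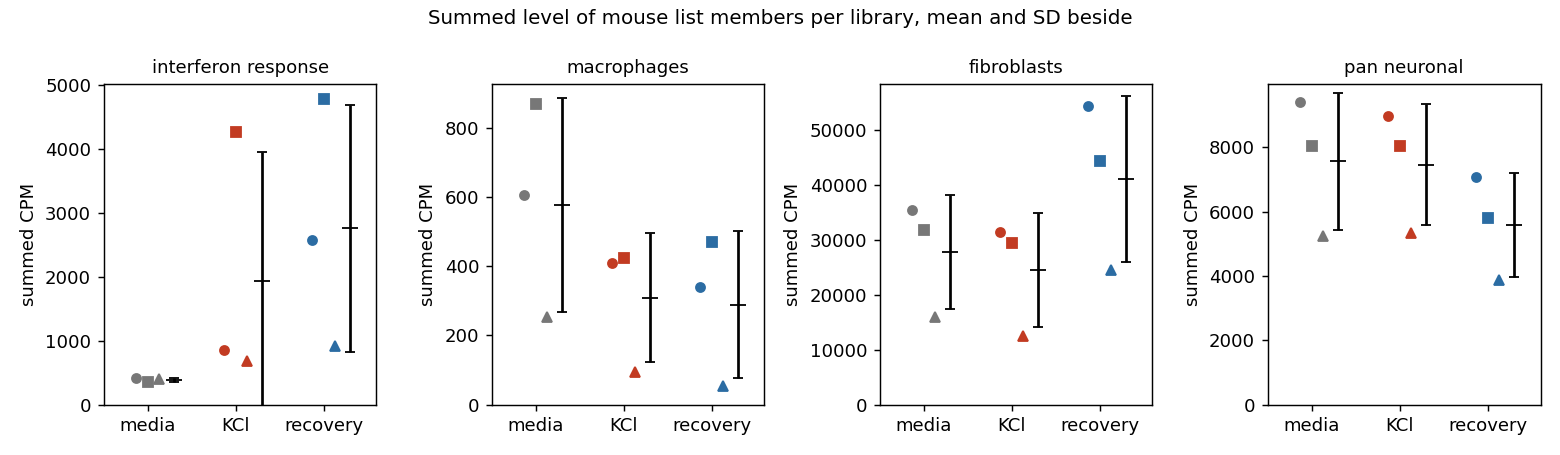
Summed CPM (y axis) of interferon response, macrophage, fibroblast and pan-neuronal marker genes in each mouse library, with symbols for replicates 1 (circle), 2 (square) and 3 (triangle), and the mean and SD of each condition beside them. Fibroblast sums were 15975 to 35458 in media and 24485 to 54240 in recovery, each recovery library lying above the media library of its number.

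**Figure D4:**
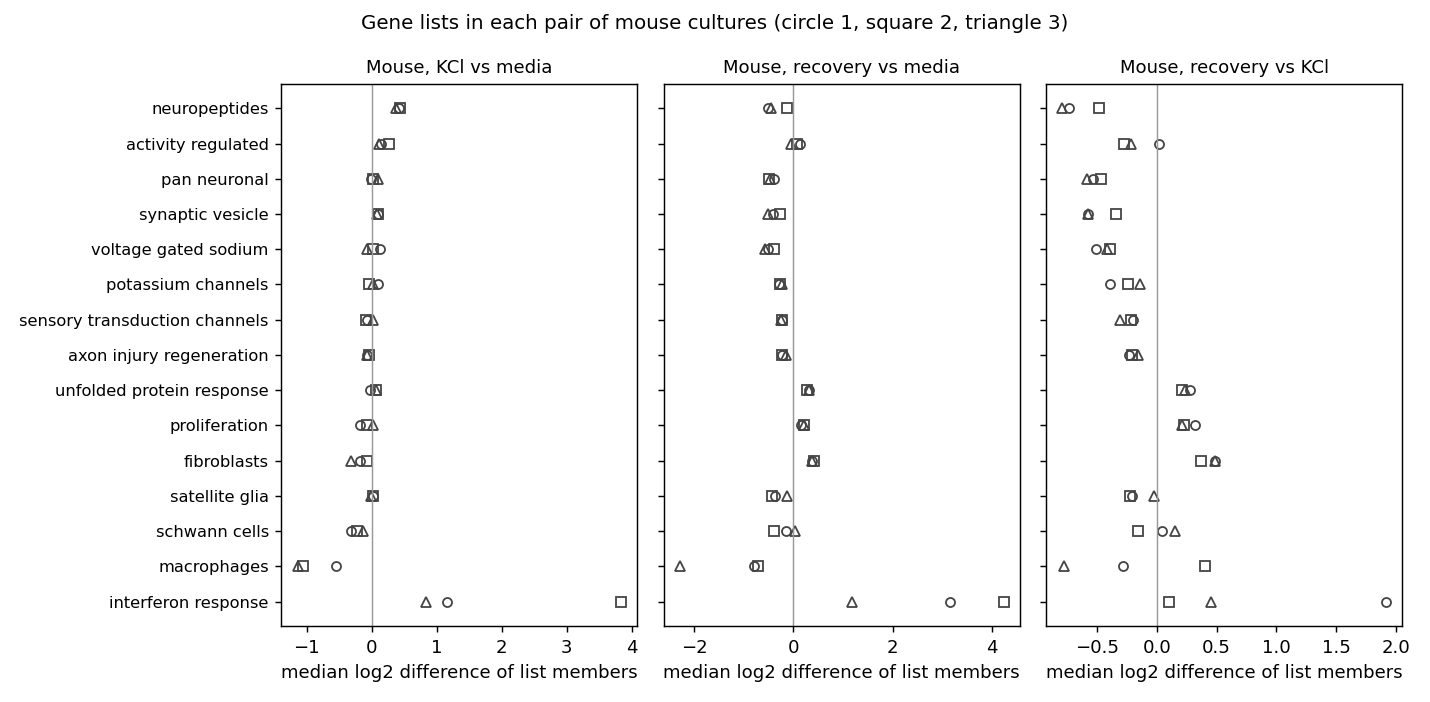
Median log2 change of the members of gene lists in each replicate pair of mouse libraries, in 1 panel per comparison, with symbols for pairs 1 (circle), 2 (square) and 3 (triangle). Pan-neuronal medians of recovery against media lay between -0.38 and -0.49, and those of the interferon list between 1.18 and 4.23.

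Recovery was compared with KCl to see which transcripts moved once KCl was removed. In mouse, most neuropeptide genes fell. Tac1 fell by 1.32 ± 0.141 (edgeR adjusted p = 5.16e-05), Calca by 0.52 ± 0.0786 (adjusted p = 0.000426), Adcyap1 by 0.99 ± 0.0794 (adjusted p = 7.69e-06) and Penk, the enkephalin precursor, by 1.62 ± 0.215 (adjusted p = 0.00256). Of 14 neuropeptide genes 12 fell and 0 rose, the same counts adjusted over the list alone, with a median of -0.69 (camera adjusted p = 4.12e-17, and an adjusted p of 0.0393 with an estimated correlation, or 0.0789 without the block). Among 41 activity-regulated genes 14 fell, including Bdnf (-0.59 ± 0.0999, adjusted p = 0.000906), Pcsk1 (-1.40), Vgf (-0.69), Fos (-0.91) and Npas4 (-0.79, adjusted p = 0.0354), and 4 rose, including Egr1 (0.70 ± 0.0721, adjusted p = 2.75e-05) and Egr3 (0.67), or 15 and 5 adjusted over the list alone (camera adjusted p = 0.0115, and an adjusted p of 0.377 with an estimated correlation). Trpv1 rose by 0.38 (adjusted p = 0.0389). The 14 falls became 9 without KCl replicate 3 or recovery replicate 2. The calls of Npas4 (KCl replicate 2 or 3, recovery replicate 2 or 3, adjusted p up to 0.213) and Trpv1 (KCl replicate 2 or 3, any recovery replicate, up to 0.271) ended without single libraries.

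Many neuronal genes were lower in recovery than in KCl too. Whether channel genes fell beyond neuronal genes in general was not tested. Of 22 genes expressed across neurons 14 fell and 0 rose (15 adjusted over the list alone), including Nefm (-0.85 ± 0.075, edgeR adjusted p = 1.21e-05). Of 26 synaptic vesicle genes 21 fell and 0 rose (21 and 1 adjusted over the list alone), including Syn1 (-0.63), the priming factor Unc13a (-0.78) and Snap25 (-0.80). Among channel genes 8 of 13 for sodium fell (9 adjusted over the list alone), including Fgf13 (-0.53) and Scn8a (-0.41), and 15 of 36 for potassium fell and 2 rose (17 and 4). Scn9a (-0.27, adjusted p = 0.0712), Scn10a (0.08), Scn11a (-0.09), Cacna1c (0.08) and Oprm1 (0.49) did not pass. Of 22 subtype genes 13 fell and 1 rose (14 and 2 adjusted over the list alone), of 14 calcium channel genes 5 fell (5), and of 21 sensory channels 7 fell and 2 rose (10 and 2). Camera's adjusted p was 4.12e-17 for pan-neuronal and synaptic genes, 9.37e-05 for sodium, 0.000165 for potassium, 1.24e-05 for subtype, 0.00875 for calcium and 0.0508 for sensory channels. With an estimated correlation these became adjusted p values of 0.0204, 0.0473, 0.0486, 0.104, 0.0473, 0.307 and 0.17, and the 4 under 0.05 became 0.35 (pan-neuronal), 0.19 (synaptic), 0.0557 (sodium) and 0.0557 (subtype) without the block. The falls dropped for potassium to 9 without KCl replicate 3 and 8 without recovery replicate 1, for subtype genes to 7 and 8 without the same libraries, and for sensory channels to 4 without KCl replicate 3. The 2 potassium channel rises became 0 without KCl replicate 2 or 3 or recovery replicate 2 and 1 without media replicate 3 or recovery replicate 1 or 3, and the 1 subtype rise became 0 without any media replicate, KCl replicate 2 or 3 or recovery replicate 3. The 2 sensory channel rises became 1 without media replicate 2, KCl replicate 2 or 3 or any recovery replicate. For calcium channels the falls dropped to 3 without KCl replicate 1 or recovery replicate 2 and 2 without recovery replicate 1, and Scn8a lost its call without KCl replicate 1 or recovery replicate 1 or 2 (adjusted p up to 0.169).

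Of 20 unfolded protein response genes 12 rose in recovery against KCl, including the disulfide isomerase gene Pdia6 (0.44) and Hspa5, which encodes the chaperone BiP (0.43 ± 0.082, edgeR adjusted p = 0.00193), and 1 fell, Dnajb9 (-0.31), or 15 and 1 adjusted over the list alone. Of 19 fibroblast genes 13 rose, led by Mfap5 (1.24 ± 0.0707, adjusted p = 3.45e-07) and Fn1 (0.98), and 2 fell, Dpt and Pdgfra. Adjusted over the list alone the counts were the same. Of 26 proliferation genes, which act in DNA replication and mitosis, 13 rose and 0 fell (19 adjusted over the list alone), including the ribonucleotide reductase gene Rrm2 (0.42). Camera's adjusted p was 1.68e-05, 2.14e-14 and 3.59e-06, and adjusted p values of 0.0473 (0.0557 without the block), 0.0555 and 0.168 with an estimated correlation. The gene with the smallest adjusted p without the block was Bves, which encodes a membrane protein of muscle and epithelium. Its levels were 12.2, 10.6 and 11.3 CPM in KCl replicates 1, 2 and 3 and 2.98, 3.79 and 3.76 CPM in recovery, against 6.45, 6.08 and 5.67 CPM in media (recovery against KCl -1.69 ± 0.159, adjusted p = 1.96e-05, and 0.0435 without the block). The largest rises and falls below are those within the abundance and separation limits of the rule for named genes. The rises were Abhd11os (2.21), Slc16a6 (1.81 ± 0.143, adjusted p = 7.69e-06), Stag3 (1.68), the sodium-calcium exchanger Slc8a1 (1.67), Klhl30 (1.46), Tnfsf15 (1.41), Ssc5d (1.28) and Sytl5 (1.25). The falls besides Bves and Penk were Aldh3a1 (-3.59 ± 0.261, adjusted p = 4.02e-06), Akr1c18 (-2.63), Cxcl5 (-2.10), Scara5 (-1.90), Crispld1 (-1.70) and Stc1 (-1.66). The 13 rises of proliferation genes became 8 without KCl replicate 2, and the 2 falls of fibroblast genes 0 without KCl replicate 1 or recovery replicate 1 and 1 without KCl replicate 2 or 3 or recovery replicate 2. The calls of Dnajb9 (KCl replicate 3, recovery replicate 1 or 3, adjusted p up to 0.0648), Akr1c18 (KCl replicate 3 or any recovery replicate, up to 0.104) and Stc1 (KCl replicate 1 or 2 or any recovery replicate, up to 0.169) ended without single libraries. So did those of Dpt (KCl or recovery replicate 1 or 3, up to 0.108) and Pdgfra (KCl or recovery replicate 1 or 2, up to 0.199). Hspa5 lies on chromosome 2 from 34771970 to 34777547, plus strand (ENSMUSG00000026864.13), and Bves on chromosome 10 from 45335772 to 45372479, plus strand (ENSMUSG00000071317.4), in GRCm38.

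The mouse genes that differed between KCl and media were followed into recovery. Of the 243 genes that rose in KCl, 172 (70.8%) fell from KCl to recovery, and their median log2 change from media went from 0.584 to 0.00843, with 46 still higher than media and 32 lower. Of the 227 that fell, 101 (44.5%) rose from KCl to recovery, and their median went from -0.50 to -0.27, with 91 still lower than media and 16 higher. The difference between these shares was not tested. The genes were chosen in the same KCl libraries from which the return was measured, which gives some return with no effect. The changes from media to KCl and from KCl to recovery correlated at -0.323 across genes, where unchanged groups gave -0.509, and their covariance was -0.0449 against a simulated -0.021. Higher in both KCl and recovery than in media were 46 genes, where independent lists would share 13.4, and lower in both were 91, where 17.4 would be shared (edgeR with the block, 0 and 0 without it). Both comparisons used the same media libraries. In 20 simulations of unchanged groups, with all libraries drawn anew and each gene drawn on its own, at most 3 and 2 genes were shared. At most 9 genes passed in either comparison there, so an overlap of the observed size could not arise. The simulations therefore cannot tell how many genes the real media libraries, or genes that move together, would share. With 3 media libraries the controls could not be split, so part of the excess may come from the shared controls. Across the 15110 genes, which are not independent replicates, the changes of KCl and of recovery from media correlated at 0.535, where shared controls alone gave 0.488. Their covariance was 0.0835 against a simulated 0.0199.

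In human cultures the genes were followed only by identifier, because no human gene annotation was at hand. In KCl, ENSG00000196154.11 was at 58.0 ± 12.1 CPM against 17.8 ± 4.72 in media (SD, n = 3 each, log2 fold change 1.71 ± 0.111, edgeR with the block, adjusted p = 1.65e-06, and 0.161 without it). ENSG00000122254.6 rose from 4.72 ± 2 to 21.0 ± 7.04 CPM (2.16 ± 0.24, adjusted p = 0.000883, and 0.97 without the block). ENSG00000183908.5 fell from 10.7 ± 1.51 to 3.54 ± 0.343 CPM (-1.59 ± 0.179, adjusted p = 0.000883, and 0.132 without the block), and ENSG00000165449.11 from 2.46 ± 0.412 to 0.871 ± 0.0996 CPM (-1.50 ± 0.28, adjusted p = 0.0299, and 0.793 without the block). Of 16044 human genes tested, 104 differed between KCl and media (68 higher, 36 lower), 298 between recovery and media (122 higher, 176 lower) and 1204 between recovery and KCl (505 higher, 699 lower). Of the 68 genes higher in KCl, 50 (73.5%) fell from KCl to recovery, and of the 36 lower, 25 (69.4%) rose, again measured from the libraries in which they were chosen. The changes from media to KCl and from KCl to recovery correlated at -0.623 across genes, where unchanged groups gave -0.516, with a covariance of -0.0614 against a simulated -0.022. Higher in both KCl and recovery than in media were 7 genes (0.517 expected of independent lists) and lower in both 9 (0.395 expected). In 20 simulations of unchanged groups, with all libraries drawn anew, at most 1 and 0 were shared. At most 6 genes passed in either comparison there, so an overlap of 7 or 9 could not arise. The changes of KCl and of recovery from media correlated at 0.242 across genes, below the 0.495 that shared controls alone gave, and their covariance, 0.0192, was close to the simulated 0.0208.

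Without the block edgeR called 0 human genes in each of the 3 comparisons, where 736, 429 and 1414 had an unadjusted p under 0.05 and DESeq2 called 8, 1 and 48. In the fit with the block, the human counts depended on single libraries. The count of 104 for KCl against media became 9, 22 and 23 without media replicates 1, 2 and 3, 35 and 22 without KCl replicates 1 and 2, and 1798 without KCl replicate 3. The share of higher genes moved with it, from 68 of 104 to 847 of 1798 without KCl replicate 3, 289 of 591 with no low-count filter and 479 of 949 with only the 2 groups compared. The 298 for recovery against media became 13, 173 and 76 without media replicates 1, 2 and 3, and 90, 851 and 138 without recovery replicates 1, 2 and 3. The 1204 for recovery against KCl became 435, 600 and 2448 without KCl replicates 1, 2 and 3, and 417 and 761 without recovery replicates 1 and 3. Whether the species differed was not tested, since mouse and human genes were not matched without a human annotation at hand.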

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

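These tests were chosen after the results were seen. In mouse, spike-in control sequences took 1.33% of the counts of KCl replicate 3 (exact 95% Clopper-Pearson interval 1.32% to 1.34%, counting error only), above the 0.402% to 0.544% of the media libraries. In human, the share of unmapped reads in KCl libraries was 5.77% ± 1.08 (SD, n = 3, 4.65% to 6.79%) and lay above the media libraries at 4.34% ± 0.0491 (4.31% to 4.40%), with an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 can give.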

How the results depend on the processing

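Alternatives to the fit with the replicate block were chosen after the data were seen, and those to the fit without it before. Without a replicate block the counts of 470, 1994 and 3387 mouse genes and 104, 298 and 1204 human genes (KCl against media, recovery against media, recovery against KCl) became 0, 0, 1, 0, 0 and 0. The DESeq2 test without the block gave 28, 169 and 405 in mouse and 8, 1 and 48 in human. With no low-count filter and no block the count was 43 for mouse recovery against KCl, 4 for human KCl against media and 7 for human recovery against KCl. With only the 2 groups compared, or without any 1 of the 6 KCl and recovery libraries, the 1 mouse gene became 0 (range 0 to 0).

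In the fit with the replicate block, an added log2 fold change of at least 1 left 103, 217 and 297 mouse genes and 26, 54 and 163 human genes, fewer by construction. No low-count filter gave 1133 for mouse KCl against media and 591, 768 and 1822 in human. Only the 2 groups compared gave 949 for human KCl against media and 772 for human recovery against KCl. Leaving out 1 library gave 92 (media replicate 2) to 671 (KCl replicate 1) for mouse KCl against media, 925 (recovery replicate 1) to 1786 (recovery replicate 3) for mouse recovery against media, and 1968 (KCl replicate 3) to 3190 (KCl replicate 1) for mouse recovery against KCl. In human the ranges were 9 (media replicate 1) to 1798 (KCl replicate 3), 13 (media replicate 1) to 851 (recovery replicate 2), and 417 (recovery replicate 1) to 2448 (KCl replicate 3). Without all libraries of replicates 1, 2 and 3 the counts were 246, 59 and 381, then 696, 1028 and 1620, then 2256, 1935 and 1990 in mouse, and 44, 30 and 105, then 51, 582 and 20, then 293, 1007 and 1124 in human. The DESeq2 test with the block called 448, 1592 and 2462 mouse genes, of which 352, 1444 and 2417 were among the genes called by edgeR, and 153, 325 and 1001 human genes, of which 95, 254 and 933 were. Fewer libraries or genes explain part of the counts by construction, and otherwise the cause was not tested.

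Genes higher in both KCl and recovery than in media numbered 46 in mouse and 7 in human with the replicate block, and lower in both 91 and 9, against 0 without it. With a log2 fold change of at least 1 they were 18 and 16 in mouse and 1 and 3 in human, and unstranded counts gave 4 for human genes higher in both. Lists called by camera numbered 8, 23 and 21 without the block and 12, 24 and 21 with it. With an estimated correlation 0, 3 and 0 were called without the block and 0, 8 and 7 with it, and fry called 0, 4 and 4 without it and 2, 20 and 20 with it. The cause was not tested. Camera calls that ended without the block were synaptic vesicle (0.0444 with, 0.168 without), p53 target (0.0465, 0.168), fibroblast (0.000774, 0.21) and mural cell genes (0.0021, 0.0606) in KCl against media, Schwann cell genes (0.00963, 0.0572) in recovery against media, and cholesterol synthesis genes (0.0388, 0.0793) in recovery against KCl, where interferon genes were called without the block alone (0.0511 with, 0.00929 without). With an estimated correlation the adjusted p without the block was 0.291 for pan-neuronal, 0.188 for calcium handling and for synaptic vesicle, 0.077 for sodium pump and 0.357 for axon injury genes in recovery against media. In recovery against KCl it was 0.0557 for sodium channel, subtype and unfolded protein response, 0.0789 for neuropeptide, 0.35 for pan-neuronal, 0.602 for axon injury and 0.19 for synaptic vesicle genes, and all of these passed with the block. The block changed no other call of camera with either correlation. Of 340 values of named genes followed in the fit with the block, 301 lost their call without the block, 24 with the DESeq2 test, 19 with only the 2 groups compared, and 94, 102 and 66 without all libraries of replicates 1, 2 and 3. No called value of a named gene changed sign while past the threshold, though genes near 0, such as Cacna1c in recovery against media (-0.03 to 0.04), did. Of the mouse genes that differed between KCl and media 243 of 470 were higher, and 535 of 1133 with no low-count filter.

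For 3 libraries against 3 the 10 splits are too few for a share under 0.05. Without the block, all 10 splits gave as many genes as the real 0 in the 5 comparisons with that count (highest other 0), and 2 splits as many as the real 1 in mouse recovery against KCl (highest other 115). That split set KCl replicate 2 and recovery replicates 1 and 2 against the rest, and 114 of its 115 genes were higher there, with 23 of 23 interferon genes among them (0.175 expected), so it follows a structure of the samples. With the block, 1 split, the real one, gave as many genes in each comparison, with highest other values of 4, 0 and 12 in mouse and 0, 0 and 0 in human, and 0 among the 4 splits that part all pairs. Libraries of the compared conditions lay fully apart for 8.58%, 14.1% and 18% of mouse genes and 10.6%, 6.38% and 13.1% of human genes, where chance gives 10% if all 6 libraries are exchangeable, which paired libraries are not. Depth limits the genes with few reads, such as Cxcl9 with 1 read in media. The planned tests between species were not run, since human genes were not named without a human annotation at hand.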

Other observations

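The gene lists were fixed before the data were examined, and the tests of explanations for the 3 patterns were chosen after the results were seen.

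In mouse recovery cultures, some genes of ion pumps and calcium handling were lower than in media. Of 18 genes of the sodium pump and chloride transport 6 fell and 0 rose, or 7 adjusted over the list alone, among them Atp1b1 (-0.44, edgeR adjusted p = 0.000733). Of 36 calcium handling genes 9 fell, among them Camk1 (-0.61) and Rcan2 (-0.62), and 2 rose, Itpr2 (0.46) and Slc8a1 (0.78), or 12 and 3 adjusted over the list alone. Adjusted p values from camera were 0.000113 and 0.000454, and for both the adjusted p was 0.0488 with an estimated correlation (0.077 and 0.188 without the block). The 9 falls became 4 without media replicate 1 or 3 or recovery replicate 1, 3 without media replicate 2 and 5 without recovery replicate 2. The 2 rises became 0 without media replicate 1 or 2 or recovery replicate 1 or 2 and 1 without KCl replicate 2 or 3 or recovery replicate 3. The calls of Itpr2 (media replicate 1 or 2, recovery replicate 1 or 2, adjusted p up to 0.192) and Slc8a1 (any of the 6 libraries compared, up to 0.237) ended.

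In recovery compared with KCl, some genes of receptors, pumps and glucose use were lower. Of all 15110 mouse genes tested, 1584 rose and 1803 fell in this comparison, and the counts below were not tested against that share. Of 21 glutamate and GABA receptor genes 10 fell and 1 rose, the same counts adjusted over the list alone, among them the kainate receptor gene Grik1 (-1.26, edgeR adjusted p = 3.13e-05). Of 18 genes of the sodium pump and chloride transport 7 fell and 1 rose, again the same adjusted over the list alone, among them Atp1b1 (-0.66). Of 23 glycolysis gene identifiers, of which 2 carry the symbol Aldoa, 12 fell and 2 rose, or 14 and 2 adjusted over the list alone, among them neuronal enolase Eno2 (-0.64). Camera's adjusted p was 0.000165, 0.00167 and 0.000428, and adjusted p values of 0.0954, 0.0736 and 0.318 with an estimated correlation. Of 19 heat shock genes 7 fell, among them Hspa4l (-0.69), of 23 cholesterol synthesis genes 7 fell and 1 rose, and of 30 nuclear genes of oxidative phosphorylation 5 fell, with the same counts adjusted over each list alone. Their camera adjusted p was 0.00667, 0.0388 (0.0793 without the block) and 0.00347, and adjusted p values of 0.377, 0.599 and 0.541 with an estimated correlation. Without KCl replicate 3 the falls became 7 for glycolysis, 1 for heat shock, 3 for cholesterol synthesis and 0 for oxidative phosphorylation. Other changes were heat shock 2 without KCl replicate 2 and 3 without any recovery replicate, cholesterol synthesis 4 without KCl replicate 2 and 3 without recovery replicate 1 or 3, and oxidative phosphorylation 12, 1, 1 and 3 without KCl replicate 1, KCl replicate 2, recovery replicate 2 and recovery replicate 3. The single rises of receptor, pump and cholesterol genes each became 0 without recovery replicate 1, as did the first without any KCl replicate or recovery replicate 3, the second without KCl replicate 1 or 2, and the third without media replicate 1, KCl replicate 3 or recovery replicate 2 or 3, and the second became 2 without media replicate 2 or 3.

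Counts of several other lists rested on single libraries. They were not tested against the share of all 15110 genes, of which 1584 rose and 1803 fell in recovery against KCl. In recovery against media 833 rose and 1161 fell. Of 36 calcium handling genes 8 fell, among them Rcan2 (-0.84), and 5 rose in recovery against KCl, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.0209, and an adjusted p of 0.115 with an estimated correlation). Of 19 opioid and inhibitory receptor genes 4 fell and 1 rose, and of 23 integrated stress response genes 5 rose, led by Pycr1 (0.92), and 2 fell, with the same counts adjusted over each list alone (edgeR with the block, camera adjusted p = 0.0511 and 0.0693). In recovery against media 7 of 19 p53 target genes rose, among them Eda2r (0.69), or 8 adjusted over the list alone (camera adjusted p = 0.000454, and an adjusted p of 0.108 with an estimated correlation). In the same comparison 4 of 13 endothelial genes fell, among them Vwf (-0.75), or 5 adjusted over the list alone (camera adjusted p = 0.00963, and an adjusted p of 0.403 with an estimated correlation). The 3 most abundant endothelial genes did not pass edgeR's test. These were Cdh5 (0.225, adjusted p = 0.224), Eng (-0.112, adjusted p = 0.772) and Emcn (0.306, adjusted p = 0.144). Of 16 lymphocyte genes only 3 were expressed enough to be tested, and 0 passed. Without single libraries, p53 rises were 2 (media replicate 1 or 2), 3 (media replicate 3, recovery replicate 2) or 4 (recovery replicate 1 or 3), and endothelial falls 2 (media replicate 1, recovery replicate 1 or 2) or 1 (media replicate 3, recovery replicate 3). Calcium handling falls were 5 (KCl replicate 2, recovery replicate 1) or 4 (recovery replicate 2) and rises 3 (KCl replicate 1, recovery replicate 1 or 3) or 2 (KCl replicate 3). Receptor falls were 2 (KCl replicate 2, recovery replicate 1), receptor rises 0 (KCl replicate 3, recovery replicate 3), and stress response rises 3 (KCl replicate 2) or 9 (recovery replicate 3) and falls 1 (KCl replicate 3).

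Of 22 pan-neuronal genes 15 were lower in mouse recovery than in media, with an adjusted p of 0.0173 from camera with an estimated correlation (0.291 without the block). A lower share of neurons alone would raise glial and fibroblast markers alike, but the satellite glia median lay 0.7 below the fibroblast median (log2 difference -0.7, SD 0.18 over 3 pairs, -0.854 to -0.502), with Col1a1 at 4690 and Apoe at 495 CPM in media (the satellite glia and Schwann cell lists overlap in part, with Sox10 in both). This test reads list medians as cell shares. The fibroblast list moved both ways (13 rose and 4 fell adjusted over the list alone), so a lower share of neurons together with changes within other cells stays open. Trends with GC content and length are argued against as the whole cause, since the pan-neuronal median was -0.425 after they were removed. A larger share of fibroblasts would dilute neurons and other cells alike, and cannot be told apart here. The pan-neuronal median lay below the mean of the satellite glia, Schwann cell and endothelial medians (-0.202, SD 0.0463), but not beyond the spread once macrophage and mural cell medians were included (-0.0612, SD 0.23, -0.248 to 0.196), so the answer depends on the cell types chosen. Of 26 proliferation genes 6 rose and 0 fell in recovery against media, and 0 to 9 rose without 1 library. Camera gave an adjusted p of 5.88e-05, and 0.185 with an estimated correlation. Which cells expressed them was not measured. A larger share of fibroblasts, both cell shares changing together, regulation within neurons, and a culture that may have been a day older at collection stay open and untested.

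The 23 interferon response genes had medians above 0 in KCl and in recovery against media, and their summed level was highest in replicate 2, but 0 and 4 of them passed, and camera with an estimated correlation gave an adjusted p of 0.415 and 0.22. Replicate 2 alone is argued against, since the lower median of the pairs of replicates 1 and 3 was 0.834 in KCl and 1.18 in recovery. A larger share of macrophages is argued against in recovery, since their marker median fell (-1.26, SD 0.883, -2.28 to -0.711 in the 3 pairs), with Lyz2 at 251 and C1qa at 46.3 CPM in media. Activation of macrophages or other cells, whether by KCl or by something that differed between cultures, may account for it and was not tested.

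Of 14 neuropeptide genes 6 were higher in mouse KCl than in media, with an adjusted p of 0.151 from camera with an estimated correlation (0.228 without the block, where 0 passed). A larger share of neurons is argued against, since the neuropeptide median lay above the pan-neuronal median in each pair (0.371, SD 0.0781, 0.281 to 0.42). A larger share of the neurons that make these peptides, and regulation of the peptide genes by sustained depolarisation, stay open as hypotheses.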
